A study of Mus musculus with 4 samples.

How the data were processed

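ATAC-seq, which marks open chromatin by the insertions of the Tn5 transposase, was measured in haematopoietic stem cells (HSCs) sorted from the bone marrow of wild-type C57BL/6 male mice aged 8 weeks. Per the labels, the HSC gate was LSK (lineage-negative, Sca-1-positive, Kit-positive) and negative for CD34, CD48 and Flt3 and positive for Slam1, and it was split by surface CD93. There were 2 libraries of CD93-positive and 2 of CD93-negative HSCs. Nothing in the labels says whether the libraries of a group came from separate mice, so any spread between them may be technical.

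Each deposited file is a list of peak summits of 1 library, not pooled, with 1 line per 1-bp summit holding its chromosome, position, name and score. Per the submitters' processing notes, reads were aligned with Bowtie2, peaks were called with MACS2, and the build was mm10. Tool versions, read filters, fragment-size limits, any Tn5 shift and the caller's threshold are not given in the sources used here. The summit names, per the file contents, hold the words filtered and short, which the labels do not define. The deposited score is taken as a −log10 of a p or q value, as MACS2 writes it, and which of them it is was not stated. The lowest score of each list lay between 3.03 and 3.09. Because the authors' score is set against each library's own background, it was used mainly to rank, filter or describe summits within a list. The score minimums, and rankings by the lower or higher of the scores of 2 libraries, also took unscaled scores across lists. Scores printed side by side are not scaled between libraries. No list of regions prone to artefactual signal was used here.

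No reads, coverage or peak widths were analysed here, so the sequencing depth of each library is unknown and the only measure of yield is the length of its list. The lists held 21 and 711 summits for CD93-positive replicates 1 and 2, and 7989 and 2755 summits for CD93-negative replicates 1 and 2. Intervals of shares are exact Clopper-Pearson 95% intervals that treat summits as independent and cover counting error only.

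Groups were taken from the sample titles. The replicate numbers inside the summit names differ from those of the titles. Names in the lists titled replicates 1 and 2 carry the numbers 2 and 3 in the CD93-positive group, and 1 and 3 in the CD93-negative group. The titles were followed, and the numbers were not treated as pairing the libraries.

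Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and plots were drawn with matplotlib 3.10.9. Positions are printed 1-based on mm10. Summits of different lists were called shared when they lay within 250 bp of each other. The share expected by chance came from 1000 random placements of a list's summits on their own chromosomes. Placement was uniform and took no account of gene ends, where most summits of the longer lists lay. A share above it therefore does not show more overlap than common gene-end sites would give. Gene positions and symbols came from the RefSeq table of GRCm38.p6, the assembly behind mm10, restricted to 21887 protein-coding genes on the autosomes, X and Y. That table carries no strand, exons or UTRs. The planned promoter window therefore became a window of 1000 bp around either end of a gene, called a gene end below, and starts were not told apart from 3′ ends. All 381 entries of 14 gene lists, 364 distinct genes, matched a current symbol. The 14 lists and the main comparisons were fixed before the data were examined. The Fisher's exact tests between libraries at equal list sizes, of overlap and of gene lists, were not part of that plan. Each list was tested in each library by Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 56 tests. Such a test describes a library and not a condition. Groups were compared by exact permutation tests, two-sided, in which 2 libraries against 2 cannot give a p below 0.333. To set lists of unequal length side by side, the 711 highest-scoring summits of each CD93-negative list were also taken. The planned motif analysis was not run because no genome sequence was used here.

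Genes were named by a rule fixed beforehand. It took Cd93, up to 15 list genes with a gene-end summit in a CD93-positive library, ranked by score, and up to 15 list genes with one in both CD93-negative libraries only, ranked by the lower score. It also took the genes of the 5 highest-scoring gene-end summits of each library, and the nearest genes of the 5 highest-scoring summits of any list under 100 summits. It gave 48 genes from the gene-end parts, and the text gives examples. Alternatives were other sharing distances (100, 500 and 1000 bp), gene-end windows (500 and 2500 bp), a gene-body window with 10000 bp on either side, score minimums of 5 and 10, autosomes and X only, merging of summits within 500 bp, equal list sizes, another gene background, a replicate block and leaving out each library. On simulated data for CD93-positive replicate 2, planted shares of 50% and 90% over 711 summits came back as 50.2% and 90.0%. The planted summits lay within 100 bp of a CD93-negative one, inside the sharing distance, so this checks the counting only. For the gene lists of CD93-negative replicate 1, simulated over 21887 genes, lists with a planted odds ratio of 3 were called in 57.1% of tests, of 6 in 88.6%, and of 1 in 0%. That library alone was simulated and no under-representation was planted, while the reported tests were adjusted over all libraries together. These rates therefore do not give the power or the false-call rate of the reported tests.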

Results

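The data were 4 lists of ATAC-seq summits, 2 from CD93-positive and 2 from CD93-negative HSCs of mouse bone marrow. CD93 is a transmembrane C-type lectin-like receptor also found on endothelial and early B-lineage cells. The title of the series states the purpose as a comparison of the chromatin of the 2 HSC fractions. Read depth is unknown for every library, and the lists differed greatly in length within each group as well as between groups.

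Fewer accessible sites were listed in each CD93-positive HSC library than in either CD93-negative one. CD93-positive replicates 1 and 2 listed 21 and 711 summits, against 7989 and 2755 in CD93-negative replicates 1 and 2, so that the group means were 366 ± 488 (SD, n = 2) and 5372 ± 3701 (SD, n = 2). Both CD93-positive lists were shorter than both CD93-negative lists, and the geometric means differed 38.4-fold (log2 ratio -5.26). The difference did not pass an exact permutation test (two-sided p = 0.333, the smallest that 2 libraries against 2 can give). The lists of the CD93-positive group themselves differed 33.9-fold in length and those of the CD93-negative group 2.90-fold. CD93-positive replicate 2 was 3.87-fold shorter than the shorter CD93-negative list. Without CD93-positive replicate 1 the log2 ratio was -2.72, and without CD93-positive replicate 2 it was -7.80.

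**Figure D1:**
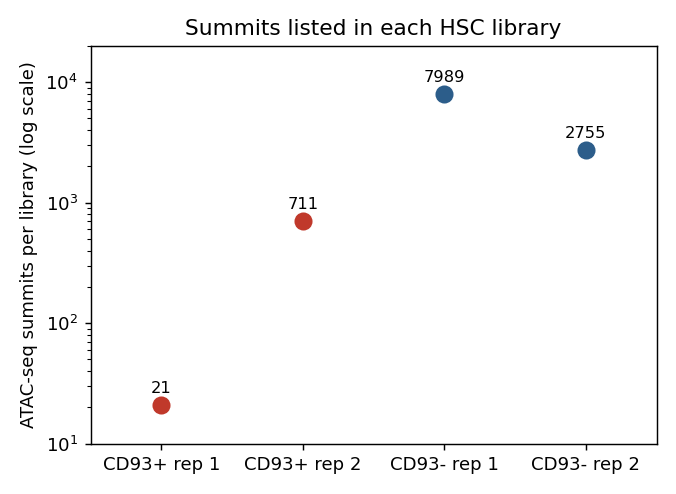
Number of ATAC-seq summits (vertical axis, log scale) listed in each HSC library (horizontal axis), with 1 point per library, red for CD93-positive and blue for CD93-negative. Both CD93-positive lists, with 21 and 711 summits, lie below both CD93-negative lists, with 7989 and 2755.

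No gene-end summit was listed at Cd93 itself (gene ID 17064, chromosome 2, 148436651 to 148443535) in any library. The summit nearest to the gene lay 78683 bp away in CD93-negative replicate 1 (score 23.5), 237575 bp away in CD93-negative replicate 2 and 229020 bp away in CD93-positive replicate 2. In CD93-positive replicate 1 the nearest summit on chromosome 2 was 49.8 Mb away. Among the 7 genes of the surface molecules used in the sort, Flt3, a cytokine receptor whose absence was part of the gate, was the only gene with a gene-end summit, in CD93-negative replicate 1 alone (score 10.8). A difference in accessibility at Cd93 between the fractions was thus not detectable in these lists.

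The longer CD93-positive list, that of replicate 2, held almost entirely sites that CD93-negative HSCs also listed. Of the 711 summits of CD93-positive replicate 2, 699 lay within 250 bp of a CD93-negative summit, or 98.3% (95% interval 97.1 to 99.1), against a mean of 0.339% after random placement and a highest value of 1.27% over 1000 placements. Random placement took no account of gene ends, where most of these summits lay, so it is a low bar. The remaining 12 summits of replicate 2 were 3 mitochondrial sites and 9 nuclear sites with scores of 4.35 to 13.1, against a median of 8.26 for the list. The nuclear site of highest score lay 539 bp outside Rap2a, a small GTPase gene, and the nearest genes of the others included Pim1, a serine/threonine kinase induced by cytokine signalling, Hspd1, a mitochondrial chaperonin, Crlf2, a cytokine receptor subunit, and Mef2a, a MADS-box transcription factor. All 9 lay within 500 bp of a CD93-negative summit. These 5 genes were chosen after their values were seen. Of the 21 summits of CD93-positive replicate 1, 10 lay within 250 bp of a CD93-negative summit, or 47.6% (25.7 to 70.2), against a mean of 1.66% after random placement. This library had only 3 gene-end summits, so most of the shared sites lay away from gene ends, among them a mitochondrial and a scaffold site. The share is thus no measure of shared HSC gene sites.

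The overlap of CD93-positive replicate 2 with each CD93-negative library was set against the overlap of the CD93-negative libraries with each other. CD93-positive replicate 2 had 97.2% of its summits near CD93-negative replicate 1, and the 711 highest-scoring summits of CD93-negative replicate 2 had 98.0%, a difference of -0.84 percentage points (95% interval -2.43 to 0.74, Fisher's exact p = 0.386). Against CD93-negative replicate 2, the share was 82.4% for CD93-positive replicate 2 and 86.8% for the 711 highest-scoring summits of CD93-negative replicate 1. That difference was -4.36 points (-8.11 to -0.61, Fisher's exact p = 0.0274). Without adjustment, the second difference passed its threshold and the first did not, and both compare libraries, not conditions. Both tests, and their normal-approximation intervals, treated the compared sets as independent. The sets had many sites in common, 332 of 711 in the first comparison and 366 of 711 in the second. Neither p therefore decides whether the shares differ. The CD93-negative lists were cut to their strongest summits, while CD93-positive replicate 2 was used down to its lowest score of 3.09. Such selection alone may give these differences and those by decile below. CD93-negative replicate 2 is the shorter reference, and of the summits away from it all but 12 lay near CD93-negative replicate 1. At equal list sizes of 711, CD93-positive replicate 2 shared 366 summits with CD93-negative replicate 1 and 332 with CD93-negative replicate 2, while the CD93-negative lists shared 385 with each other. In full, 92.9% of the summits of CD93-negative replicate 2 lay near CD93-negative replicate 1, and 32.0% the other way.

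Recovery of CD93-negative sites fell with their score. In CD93-positive replicate 2, 48.9% (95% interval 45.4 to 52.5) of the highest-scoring decile of CD93-negative replicate 1 had a summit within 250 bp, 16.8% of decile 2 and 10.0% of decile 3. In the lowest decile, 0 of 798 did. The 711 highest-scoring summits of CD93-negative replicate 2 recovered 52.3%, 20.2% and 7.51% of the same 3 deciles. For the deciles of CD93-negative replicate 2, CD93-positive replicate 2 recovered 62.0% of the highest and 2.91% of the lowest. The widest gap from the equally long CD93-negative list was in decile 2 of this list, with 39.5% against 49.6%, while for CD93-negative replicate 1 it was 3.38 points, in deciles 1 and 2. CD93-positive replicate 2 recovered more in deciles 3 and 5 to 9 of CD93-negative replicate 1, and in deciles 7 to 10 of CD93-negative replicate 2, as in decile 8 of the latter with 10.2% (6.87 to 14.4) against 2.55% (1.03 to 5.17).

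**Figure D2:**
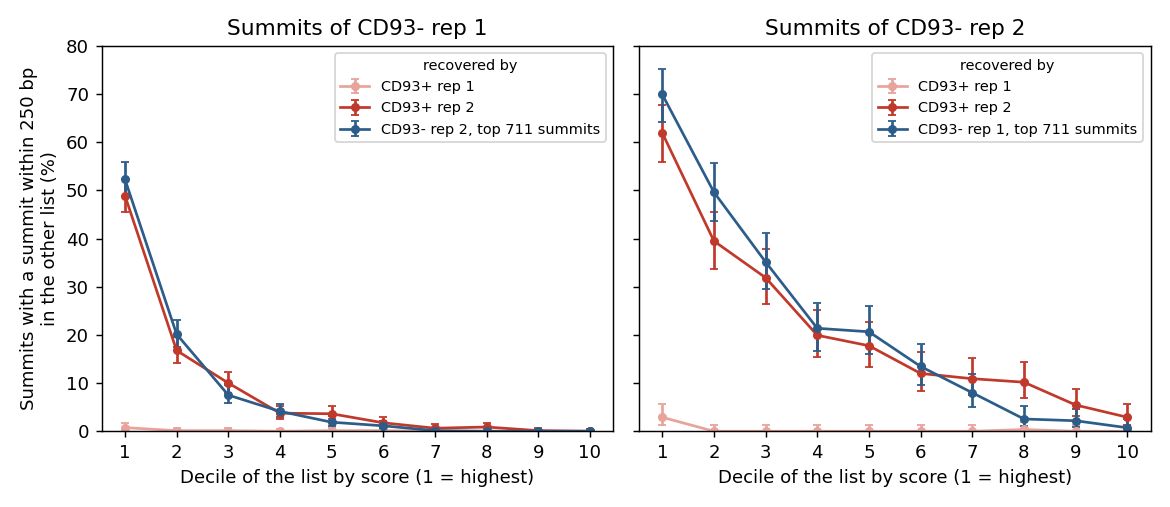
Percentage of the summits of CD93-negative replicate 1 (left) and replicate 2 (right), in deciles of their own scores with 1 the highest (horizontal axis), that had a summit within 250 bp in CD93-positive replicate 1 (pale red), CD93-positive replicate 2 (red) or the 711 highest-scoring summits of the other CD93-negative library (blue). Bars are exact 95% intervals. Recovery by CD93-positive replicate 2 falls from 48.9% to 0% on the left and from 62.0% to 2.91% on the right.

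CD93-positive replicate 1 held few sites at genes. Of its 21 summits, 8 were present in all 4 lists and 11 in no other list. The site of highest score in every list was on chromosome 2 at 98667135, over 1 Mb from the nearest gene, Lrrc4c. Its scores were 869.95 and 2136 in CD93-positive replicates 1 and 2 and 2976 and 2097 in CD93-negative replicates 1 and 2. Other sites in all 4 lists were at 35305455, 3024455 and 3000536 on chromosome 9 (nearest genes Rpusd4, 29498 bp away, and Alkbh8, 310776 and 334695 bp away), at 12847 on the mitochondrial genome and on the unplaced scaffold JH584304.1. Scores at these sites exceeded the median of each list (4.38 to 20.6). No list of regions prone to artefactual signal was used, so artefact there cannot be excluded. The nearest genes are given for position only. A further site in all 4 lists, at 124801862 on chromosome 14, lay 124176 bp from Fgf14. It scored 5.52 and 9.65 in CD93-positive replicates 1 and 2, and 20.51 and 7.35 in CD93-negative replicates 1 and 2. The last 2 scores lay below the medians of their lists, 20.60 and 9.81. The single gene-end site among the 8 was at 67008927 on chromosome 14, 50 bp outside Bnip3l, a mitophagy receptor gene, with scores of 4.71 and 6.94 in the CD93-positive and 37.2 and 22.0 in the CD93-negative libraries. The other gene-end summits of this library lay 161 bp outside Snapc1 and inside Ogfod1, 250 bp from its neighbour Nudt21, with scores of 3.05 and 3.36. In this list, 8 summits carried the identical score of 3.36. Mitochondrial summits numbered 2 and 8 in CD93-positive replicates 1 and 2, or 9.52% and 1.13% of their lists, and 5 and 3 in CD93-negative replicates 1 and 2, or 0.063% and 0.109%.

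In the other libraries most accessible sites lay at gene ends. The share within 1000 bp of either end of a protein-coding gene was 82.6% (95% interval 79.6 to 85.3) in CD93-positive replicate 2, 75.6% (74.6 to 76.5) in CD93-negative replicate 1 and 83.0% (81.6 to 84.4) in CD93-negative replicate 2, against 3.09% to 3.20% after random placement. It was 14.3% (3.05 to 36.3) in CD93-positive replicate 1, whose 21 summits are set against the 21 highest-scoring of each other list by shares of 0% in CD93-positive replicate 2 and 38.1% and 23.8% in CD93-negative replicates 1 and 2. The group means, 48.4% ± 48.3 (SD, n = 2) and 79.3% ± 5.27 (SD, n = 2), gave p = 0.667 in an exact permutation test, which could not go below 0.333. With 21 summits from each list the difference was -23.8 points, and the shares of the groups did not overlap (exact permutation p = 0.333). That separation rested on 3 summits in CD93-positive replicate 1 against 5 in CD93-negative replicate 2. Their 95% intervals, 3.05 to 36.3 and 8.22 to 47.2, overlapped widely. The whole list of CD93-positive replicate 1 was here set against the strongest summits of the others. The difference of -30.9 points became 3.24 points without CD93-positive replicate 1. At equal lengths of 711 summits the shares of the 3 longer lists were 82.6%, 84.1% and 84.5%. In CD93-negative replicate 1 the share fell from 85.2% in the highest-scoring decile to 55.3% in the lowest.

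The gene-end sites of highest score in CD93-positive replicate 2 were at Lars2 (mitochondrial leucyl-tRNA synthetase, score 38.6, at 123462025 on chromosome 9, inside the gene 650 bp from its end), Atp2b1 (a plasma-membrane calcium pump, 24.3), Rad23b (a nucleotide excision repair factor, 21.9), Cacybp (21.7) and Ripk2 (a kinase of innate immune signalling, 21.6). All 5 also had summits in both CD93-negative libraries, with scores of 54.7 to 99.4 in replicate 1 and 19.8 to 34.0 in replicate 2. In CD93-negative replicate 1 the highest were Ccnyl1 (140.4), Fzr1 (an activator of the anaphase-promoting complex, 136.2), Ankrd11 (129.6), Etf1 (a translation release factor, 127.96) and Cycs (cytochrome c, 125.6). Of these, Cycs was the single gene without a summit in CD93-positive replicate 2, and its score in CD93-negative replicate 2 was 8.98. In CD93-negative replicate 2 they were Lars2 (34.0), Hjurp (a centromere histone chaperone, 31.0), Larp1b (30.9), Tbl2 (30.3) and Mrps14 (a mitochondrial ribosomal protein, 30.0), each also listed in CD93-positive replicate 2.

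Among the fixed gene lists, housekeeping, cell-cycle and stress genes passed as over-represented in both CD93-negative libraries. None of the 3 lists passed in either library with 711 summits per list, where the odds ratio of the housekeeping list was 1.56 in replicate 1 and 3.19 in replicate 2. That of the cell-cycle list was then 0.95 and 0.92, and that of the stress list 6.46 and 2.20. Against a background of genes with a gene-end summit in any library, none of the 3 passed either, although nearly every such gene carried a summit in replicate 1. With replicate 1 reduced to its 2755 highest-scoring summits, the stress list passed in neither library over the 56 tests (odds ratios 3.19 and 3.20). In CD93-negative replicate 1, which reached 7042 of the 21887 genes (32.2%), gene-end summits were found at 34 of 40 ribosome and housekeeping genes (odds ratio 12.0, Fisher's exact test with Benjamini-Hochberg adjusted p = 3.9e-10). By the same exact test they were found at 22 of 32 cell-cycle genes (4.65, adjusted p = 0.00046), 21 of 28 p53, repair and stress genes (6.34, adjusted p = 0.00011), 21 of 30 mitochondrial and metabolic genes (4.93, adjusted p = 0.00046) and 18 of 31 quiescence and dormancy genes (2.92, adjusted p = 0.0226). The last list did not pass in CD93-negative replicate 2 (8 of 31, 2.35, exact test, adjusted p = 0.198), nor in replicate 1 reduced to its 2755 highest-scoring summits (2.34, exact test, adjusted p = 0.225). In replicate 1 the covered genes included Klf6, Btg2, Cdkn1b, Foxo1, Foxo3 and the immediate-early genes Jun, Fos and Egr1. Other genes of the list, among them Cdkn1a, Cdkn1c, Ndn, Gprc5c, Rarb, Cyp26b1 and Neo1, had no gene-end summit in any library. CD93-negative replicate 2 reached 2829 genes (12.9%), and over-representation passed the exact test there for ribosome and housekeeping genes (15 of 40, odds ratio 4.06, adjusted p = 0.00084), cell-cycle genes (11 of 32, 3.54, adjusted p = 0.0125) and p53, repair and stress genes (9 of 28, 3.20, adjusted p = 0.0382). With a score of at least 5, the cell-cycle list did not pass in this library (exact test, adjusted p = 0.0650), nor did the stress list, which also failed with a window of 2500 bp (exact test, adjusted p = 0.0664 and 0.0582). The mitochondrial and metabolic list, with 9 of 30 genes, did not pass there (exact test, adjusted p = 0.0549). Nor did it pass in replicate 1 with 711 summits, where its odds ratio was 2.11. Chromatin regulators did not pass, with 17 and 8 of 32 (exact test, adjusted p = 0.0598 and 0.205), among them Ezh2 and Suz12 of Polycomb complex PRC2. They passed in replicate 1 with a window of 2500 bp and in both libraries with the gene-body window (exact test, adjusted p = 0.0011, 0.00025 and 0.00051).

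Markers of other cell types differed by list. None of the 24 endothelial and stromal genes had a gene-end summit in any library, which was fewer than among other genes in CD93-negative replicate 1 (exact test, adjusted p = 0.0010) and did not pass in replicate 2 (adjusted p = 0.211). Mature blood cell genes numbered 2 of 28 in CD93-negative replicate 1 (odds ratio 0.162, exact test, adjusted p = 0.0226), namely Xbp1 and Cd68, and 1 of 28 in replicate 2, which did not pass (0.249, exact test, adjusted p = 0.587). Neither list passed when replicate 1 was reduced to its 2755 highest-scoring summits, a setting added after seeing the data, with 0 of 24 and 0 of 28 genes covered (exact test, adjusted p = 0.225 and 0.217). The 26 myeloid genes had 10 in CD93-negative replicate 1 (exact test, adjusted p = 1) and included the granule and alarmin genes S100a8, S100a9, Ngp and Camp, of which S100a8 was also in CD93-negative replicate 2. The granule genes Mpo, Elane, Ctsg, Prtn3 and Ltf of the same list had no gene-end summit in any library. The megakaryocyte and erythroid list had 6 of 28 (exact test, adjusted p = 0.645), with Nfe2, Zfpm1 and Tfrc, and the lymphoid list 4 of 28 (adjusted p = 0.174), with Flt3 and Tcf3. HSC identity genes numbered 7 of 37 in CD93-negative replicate 1, among them Tal1, Lyl1, Etv6 and Msi2, and 1 in replicate 2, Egr1. Neither passed a test against other genes (odds ratios 0.491 and 0.187, exact test, adjusted p = 0.328 and 0.252). The list named for complement and the CD93 family had 1 of 10 genes in each CD93-negative library, Hmgb1. Cd93, Thbd, Clec14a, Cd248, C1qa, C1qb and C1qc of that list had no gene-end summit in any library.

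CD93-positive replicate 2 reached 704 genes (3.22%), and 14 of the 364 list genes were among them. The 4 with the highest scores were Klf6 (a zinc-finger transcription factor, summit at 5861306 on chromosome 13, 183 bp outside the gene, score 20.4), Hspa8 (a constitutive heat-shock chaperone, 12.5), Atm (the DNA double-strand break kinase, 9.71) and Tgfbr1 (a TGF-β receptor, 8.38, equal to the cyclin gene Ccna2). The others were Stk11 and Lamtor1 of nutrient and energy sensing, Zfpm1, Ctcf, Atr, the circadian clock gene Per3 of the myeloid list, Kat6a, Hspa1b and Tfrc. Each of the 14 had a gene-end summit in CD93-negative replicate 1, and 12 had one in replicate 2, the exceptions being Atr and Hspa1b. Hspa1b has a near-identical neighbour, Hspa1a, so its reads are uncertain. No list passed in either CD93-positive library. In replicate 2 the p53, repair and stress list, with 4 of 28 genes, had an odds ratio of 5.04 (Fisher's exact test, adjusted p = 0.0549) and was the 1 list of 14 with an unadjusted p under 0.05. In replicate 1 there was none. HSC identity and ribosome and housekeeping genes had 0 of 37 and 0 of 40 in replicate 2.

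A further 53 list genes had gene-end summits in both CD93-negative libraries and in neither CD93-positive one. By the lower of their scores the first were Rps19 (31.0 and 19.8 in CD93-negative replicates 1 and 2), Mki67 (the proliferation marker, 26.9 and 18.0), Rpl13a (52.7 and 17.2), Nfe2l2 (the oxidative-stress regulator NRF2, 40.6 and 15.3), Btg2 (an antiproliferative gene, 80.7 and 14.96), Rplp0 (47.1 and 14.9) and Atp5b (36.9 and 14.3). Cell-cycle genes in this set included Mcm4, Aurka, Cdk4 and Pcna. Absence of these genes from the shorter CD93-positive lists may reflect list length alone. At equal list sizes the differences between CD93-positive replicate 2 and each CD93-negative library in the fixed lists did not pass, and these tests compare libraries, not groups. Of the 711 highest-scoring summits, those of CD93-negative replicates 1 and 2 covered 2 and 4 ribosome and housekeeping genes against 0 in CD93-positive replicate 2, 1 and 1 cell-cycle genes against 1, and 5 and 2 p53, repair and stress genes against 4. Over 28 such comparisons the smallest Fisher's exact p was 0.125 and every adjusted p was 1. With so few list genes in each, these counts cannot exclude differences.

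**Figure D3:**
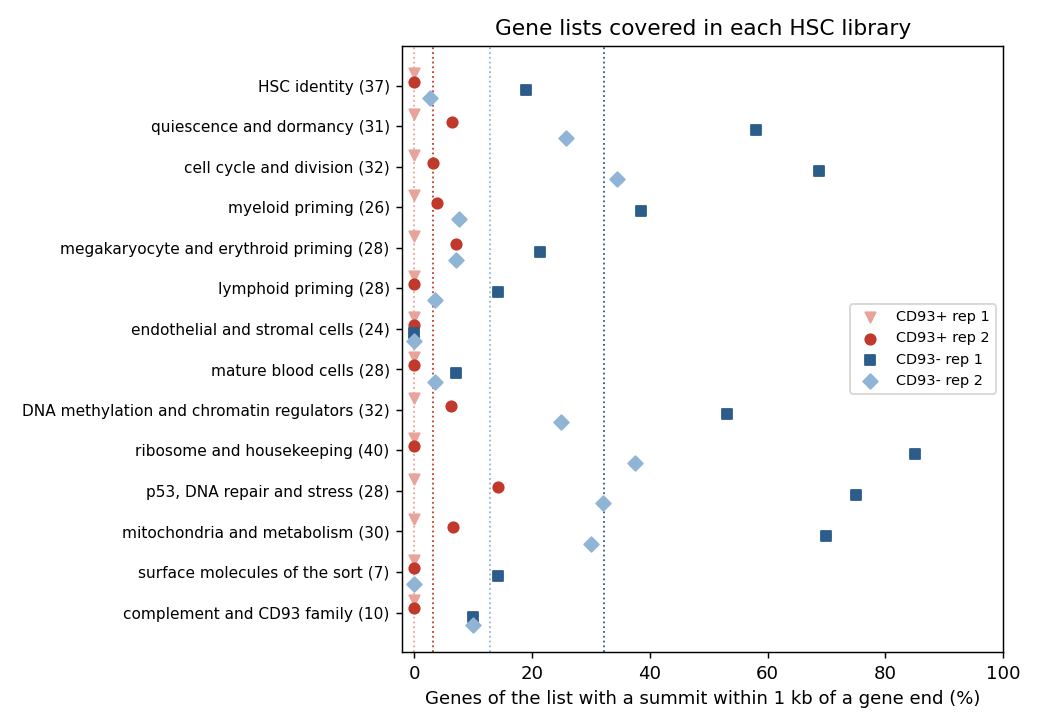
Percentage of the genes of each list (rows, list size in brackets) with a summit within 1 kb of a gene end (horizontal axis), with 1 marker per library, shifted vertically for clarity. Dotted lines give the percentage among the remaining genes in the library of the same colour. In CD93-negative replicate 1, 85.0% of ribosome and housekeeping genes and 0% of endothelial and stromal genes were covered, against about 32.2% of other genes.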

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

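The number of summits kept its direction under every alternative run (log2 ratios from -6.16 with a score of at least 10 to -5.26 with nearby summits merged), with a range of -7.80 to -2.72 when each library was left out, and its test could not pass in any of them. With the replicate number as a replicate block the log2 ratio was -5.26 (exact sign-flip p = 0.5, the smallest that 2 pairs allow). The numbers do not pair the libraries by any label, so the paired value is given for completeness. The share of CD93-positive summits near CD93-negative ones stayed above random placement under every alternative, a low bar because placement took no account of gene ends. It ranged from 82.4% to 97.2% for replicate 2 and from 42.9% to 47.6% for replicate 1 when each CD93-negative library was left out, and replicate 1 moved to 87.5% with a score of at least 5, where 8 summits remained, all away from gene ends. Recovery of the highest-scoring decile of CD93-negative replicates 1 and 2 moved from 48.9% to 42.8% and from 62.0% to 51.4% with a distance of 100 bp, an alternative added after seeing the data. The difference in gene-end share ranged from -65.0 to 3.24 percentage points over the libraries left out and turned to 3.24 without CD93-positive replicate 1.

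Gene-list calls depended on list length and on other settings. With equal lists of 711 summits, 0 lists were over-represented and 0 under-represented in CD93-negative replicate 1 (5 and 2 before) and 0 were over-represented in replicate 2 (3 before), with fewer genes carrying a summit by construction. The odds ratio of the cell-cycle list then turned to 0.95 and 0.92 in CD93-negative replicates 1 and 2, and those of the housekeeping list fell to 1.56 and 3.19 (12.0 and 4.06 before). In replicate 1 the mitochondrial list fell to 2.11 (4.93 before), while the stress and the quiescence lists had 6.46 and 3.17 (6.34 and 2.92 before), and in replicate 2 the stress list fell to 2.20 (3.20 before). With genes that had a gene-end summit in any library as background, these counts were likewise 0, 0 and 0. The quiescence and dormancy list turned to an odds ratio of 0.11 in replicate 1, where nearly every background gene carries a summit by construction. That reason does not hold for replicate 2, where the cell-cycle list fell to 1.51 (3.54 before). Over-representation there was thus not detected among genes with a gene-end summit in any library. With CD93-negative replicate 1 reduced to its 2755 highest-scoring summits, added after seeing the data, 3 lists were over-represented and 0 under-represented there, and the p53, repair and stress list passed in neither library (odds ratios 3.19 and 3.20, exact test, adjusted p = 0.0550 in both over 56 tests, and 0.0275 over the tests of these 2 libraries alone). The gene-body window gave 1 under-represented list in CD93-negative replicate 2, HSC identity, where 0 had passed, and made the chromatin regulators over-represented in both CD93-negative libraries (odds ratios 5.64 and 4.41), as the 2500 bp window did in replicate 1 (4.08). With a score of at least 5, the cell-cycle and the p53, repair and stress lists lost their calls in replicate 2 (odds ratios 2.84 and 2.90) and the mitochondrial and metabolic list gained one (3.11). The cause was not tested. Of 48 named genes, 6 were listed in fewer libraries with a score of at least 5, and none moved with the 2500 bp or gene-body windows. The planned motif comparisons, 21 motifs with their own alternatives, were not run because no genome sequence was used here. Unknown read depth limits every absence reported, above all in CD93-positive replicate 1.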

Other observations

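Many sites that both CD93-negative libraries listed were in neither CD93-positive list, as list length alone requires. The CD93-positive lists held 21 and 711 summits, too few to match most sites shared by the CD93-negative libraries. Such absences do not show sites closed in CD93-positive HSCs. Of the 2560 summits of CD93-negative replicate 2 shared with CD93-negative replicate 1, 1982 had no CD93-positive summit within 250 bp. By the lower of their scores the strongest were at Mtrf1l (a mitochondrial release factor, scores 61.4 and 29.5 in CD93-negative replicates 1 and 2), Traf7 (47.6 and 28.4), a site 16877 bp outside Chd2, a chromatin remodeller (91.1 and 28.0), Phf19, a Polycomb-associated factor (58.8 and 27.7), Slc35e1 (92.9 and 27.6), Ccnt2, a cyclin of the transcription elongation factor P-TEFb (85.1 and 26.8), Grk6, a kinase of G protein-coupled receptors (54.1 and 25.9), and Gins2, a DNA replication factor (80.4 and 25.2). These were chosen by their scores after the data were seen. Among HSC identity genes, Runx1 and Erg had no gene-end summit, yet each had a summit in CD93-negative replicate 1 away from gene ends, in the gene or up to 10000 bp outside it (scores 8.84 and 9.44), as did Tal1 (6.15) and Etv6 (8.04).

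The tests of explanations given next, on the nested CD93-positive lists and on HSC identity genes, were chosen only after those patterns were seen.

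The CD93-positive lists were short and, in replicate 2, nested in the CD93-negative lists. Sites that CD93-negative HSCs lack are argued against among those listed in CD93-positive replicate 2, where 1.69% of the summits (95% interval 0.875 to 2.93) lay near neither CD93-negative list, under a bound of 5% set afterwards, and the 9 nuclear ones all lay within 500 bp of a CD93-negative summit, although this share restates the overlap that defines the pattern and is no separate test. In CD93-positive replicate 1 the share was 52.4% (29.8 to 74.3), but 0 of these 11 sites recurred in replicate 2, 10 of them scored only 3.36 to 4.38 and the other was mitochondrial, and whether this list of 21 summits is complete is unknown, so this remains open there, as it does for sites too weak to be listed. A candidate explanation is a shallower or less enriched library that lists the strongest sites of the same landscape, for which the values were mixed: recovery by decile differed from that of the equally long CD93-negative list by at most 3.38 points for CD93-negative replicate 1, where both lists recovered under 5% of deciles 4 to 10 and a gap of 10 points was out of reach there, and by up to 10.1 for replicate 2, against a bound of 10, and was higher in several lower-scoring deciles of both. A longer list cut to its strongest summits is not the same as a shallower library, so these gaps cannot decide the question. Lower accessibility across the genome in CD93-positive HSCs cannot be told apart from a shallower library, because read depth is unknown and the exact permutation test of list length gave p = 0.333, the lowest possible.

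HSC identity genes seldom carried a gene-end summit in CD93-negative replicate 1 (7 of 37), which might come from gene lengths and the limited number of summits alone. Random lists matched on gene length had a median of 11 such genes (middle 95%, 6 to 17), and a two-sided share of 0.154 of 10000 such lists were as extreme, so the count lay within their range. This does not show gene length to be the reason, since the unmatched test did not pass either (exact test, adjusted p = 0.328). CD93-negative replicate 2, with 1 of 37 genes (odds ratio 0.187), was not tested this way. There the list passed as under-represented with the gene-body window (exact test, adjusted p = 0.0403). The hypothesis that the open sites of these genes lie away from gene ends gained no support, with 4 genes against a median of 3 in random lists, of which a share of 0.488 had as many or more, and so few genes leave it open.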
